A study of Drosophila melanogaster with 8 samples.

How the data were processed

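Poly-A selected RNA was sequenced from S2R+ cells, a macrophage-like Drosophila melanogaster line derived from embryos, and from an S2R+ line whose Stat92E gene was disrupted with CRISPR. Cells of both lines were given control media or the ligand upd for 1 hour, and each of the 4 groups holds 2 libraries. Per the labels' protocols, RNA was extracted with Trizol and libraries were made with the Wafergen PrepX kit on an Apollo instrument. Reads were trimmed or aligned with tools that include Trimmomatic 0.36 and STAR 2.5.2b on the dm6 assembly, per the submitters' processing notes. The read counter, its annotation release, its strand setting and any filter on reads are not given in the sources used here. Reads of overlapping genes, antisense partners and near-identical copies therefore cannot be told apart for certain.

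Each library has its own deposited table with a count, a length and an RPKM value for 13932 FlyBase gene identifiers. The deposited count column holds whole numbers whose totals differ between libraries. The RPKM column was made by the authors from the same counts, because dividing one by the other and by the gene length gives a single constant per library. That constant exceeds the library's gene total, so the authors scaled RPKM to a larger number of reads. Which reads make up the rest is not given. Gene totals were between 85.2% and 90.6% of that constant. Symbols and dm6 coordinates came from an Ensembl annotation of the same assembly, which matched 13852 identifiers and left 80 without a symbol.

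Library totals ranged from 8285533 to 30352948 counts. The detection floor was set at 3 counts, which is between 0.0961 and 0.379 CPM (counts scaled to the normalised size of the library) in single libraries. A fold against a group with 0 counts was computed against 3 counts over that group's libraries and is a lower bound. Where a group held 1 to 3 counts in all, the ratio of counts is given with its 95% interval. These intervals and floors cover counting error only. The comparisons, tests, gene lists, rule for naming genes and first set of alternatives were chosen before the data were examined. That plan used limma on log2(RPKM + 1) unless the tables held raw counts, and named edgeR for that case. The tables held counts, so the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 was used, with TMM scaling, the filterByExpr filter, 4 group means and all 8 libraries in 1 fit. That left 8126 genes and 4 residual degrees of freedom, with a median biological coefficient of variation of 21.2%. Tests were two-sided, p-values were adjusted by Benjamini and Hochberg's method, and the threshold was an adjusted p of 0.05. The comparisons were upd against control media in each line, the difference of these responses (an interaction term), and the mutant line against the wild-type line in each medium.

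The gene lists of the plan were 30 lists with 672 symbols covering signalling pathways, stress responses, cell type markers and basic cell functions. Of these symbols, 637 were resolved and 624 genes were in the tables. Several lists share members. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01 between genes, adjusted over the lists within a comparison, and again with an estimated correlation. The Turandot list had 0 members left after the filter, so 29 lists were tested. The rule for naming genes took the 10 largest changes in each direction among genes that passed and did not overlap between groups. The rule added up to 5 genes with the lowest p where fewer than 5 passed, Stat92E, members of the JAK/STAT lists, and up to 4 members of each other list. CG15097, mgl, loco, foi, CG15673 in wild-type cells, TP53INP and stg, genes named for the difference between lines with a separate replicate term, and the neighbouring genes named among the other observations fall outside that rule. They were chosen after their values were seen.

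The wild-type libraries fell into a shallow and a deep batch that coincide with replicate numbers. After the data were seen, a fit of the 4 wild-type libraries with this batch as a term was added, which tested 7748 genes and leaves 1 residual degree of freedom. A fit of all libraries with the replicate number as a separate term within each genotype was added for the same reason. Between the lines, this fit compares the levels of replicate 1 and leaves the spread between replicates of a line out of the error. Its calls between lines are therefore not tested against that spread. List tests after quantile normalization were added after the data were seen too. Quantile normalization gives equal ranks equal values in every library. It therefore removes part of any shift shared by the most abundant transcripts, such as mitochondrial and ribosomal ones, by construction. Other alternatives were DESeq2 1.42.0, median-of-ratios scaling, no filter, a filter on mean RPKM of at least 5, limma on log2 RPKM with several pseudocounts, other priors, a replicate block, and leaving out each library in turn. With 1 library left in a group, its variance is assumed to be like that of the other groups.

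The fit of all libraries, the wild-type fit with depth batch and the fit with the replicate number within genotype were tested on simulated counts with 200 changed genes, and DESeq2 and limma were not. The counts were drawn from the fit with the replicate number within genotype, with its replicate terms and dispersions, so that model is true in them by construction. The rates hold under that model and do not show that replicate numbers pair the real libraries or how often calls there are false. The fit of all libraries recovered 32.7% of the 2-fold and 72.4% of the 4-fold changes simulated for the upd response in wild-type cells, with 0 false calls among 103. For the mutant response it recovered 17.3% and 71.7%, for the difference between lines 1.02% and 50%, and for the lines in control media 21.4% and 70.7%, with 0 false calls in each. The wild-type fit with the depth batch recovered 86.7% of the 2-fold changes, and 13 of its 188 calls were false. The fit with the replicate number within genotype recovered 86.7% of the 2-fold changes for wild-type cells (6 of 180 calls false), 84.7% for the mutant line (12 of 191), 72.4% for the difference between lines (5 of 163) and 77.6% for the lines in control media (3 of 164). Replicates of every group differed by more than sampling noise, with a chi-square per degree of freedom from 27.6 to 96.8 where 1 is pure counting error. GC content was not analysed here because no sequence was used.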

Results

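The 8 libraries measure polyadenylated transcripts of cultured Drosophila cells an hour after a cytokine was added. Unpaired (upd) is a secreted ligand that binds the receptor Domeless and, through the kinase Hopscotch, activates the transcription factor STAT92E. S2R+ cells (wild type) and an S2R+ line with a CRISPR mutation of Stat92E (mutant) were each treated for 1 hour with control media or upd, with 2 libraries in each of the 4 groups. The comparisons ask which transcripts are targets of JAK/STAT signalling in these cells and which of their changes need STAT92E. Wild-type libraries of replicate 1 held 8285533 counts in control media and 9142736 with upd, and those of replicate 2 held 28465332 and 30352948. Mutant libraries held 20132421 and 15146225 counts in control media and 21600752 and 22948539 with upd. Transcripts encoded by the mitochondrial genome took 20.2% and 22.1% of the counts in the shallow wild-type libraries and 13.95% and 12.84% in the deep ones. In the mutant line their share was 15.0% and 15.1% in control media and 19.1% and 17.0% with upd. The labels do not say whether replicates are separate cultures, so p-values measure the spread between these libraries, which may be technical.

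Stat92E (FBgn0016917, chromosome arm 3R, 20535323 to 20552311 on dm6) was transcribed in both lines. Its level was 161 and 178 CPM, a count scaled to library size, in wild-type cells in control media and 157 and 160 CPM with upd. In the mutant line it was 103 and 114 CPM in control media and 111 and 121 CPM with upd. The level in control media fell by 0.65 ± 0.14 on the log2 scale (SE, n = 2 per group) between the lines, with an adjusted p of 0.0253. With upd the difference was -0.45 ± 0.14 and did not pass, with an adjusted p of 0.0801. A small edit need not lower the transcript, so this level does not measure the protein. The call in control media was lost without any single control-media library: the log2 difference was -0.72 without wild-type replicate 1, -0.57 without wild-type replicate 2, -0.575 without mutant replicate 1 and -0.715 without mutant replicate 2.

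**Figure D1:**
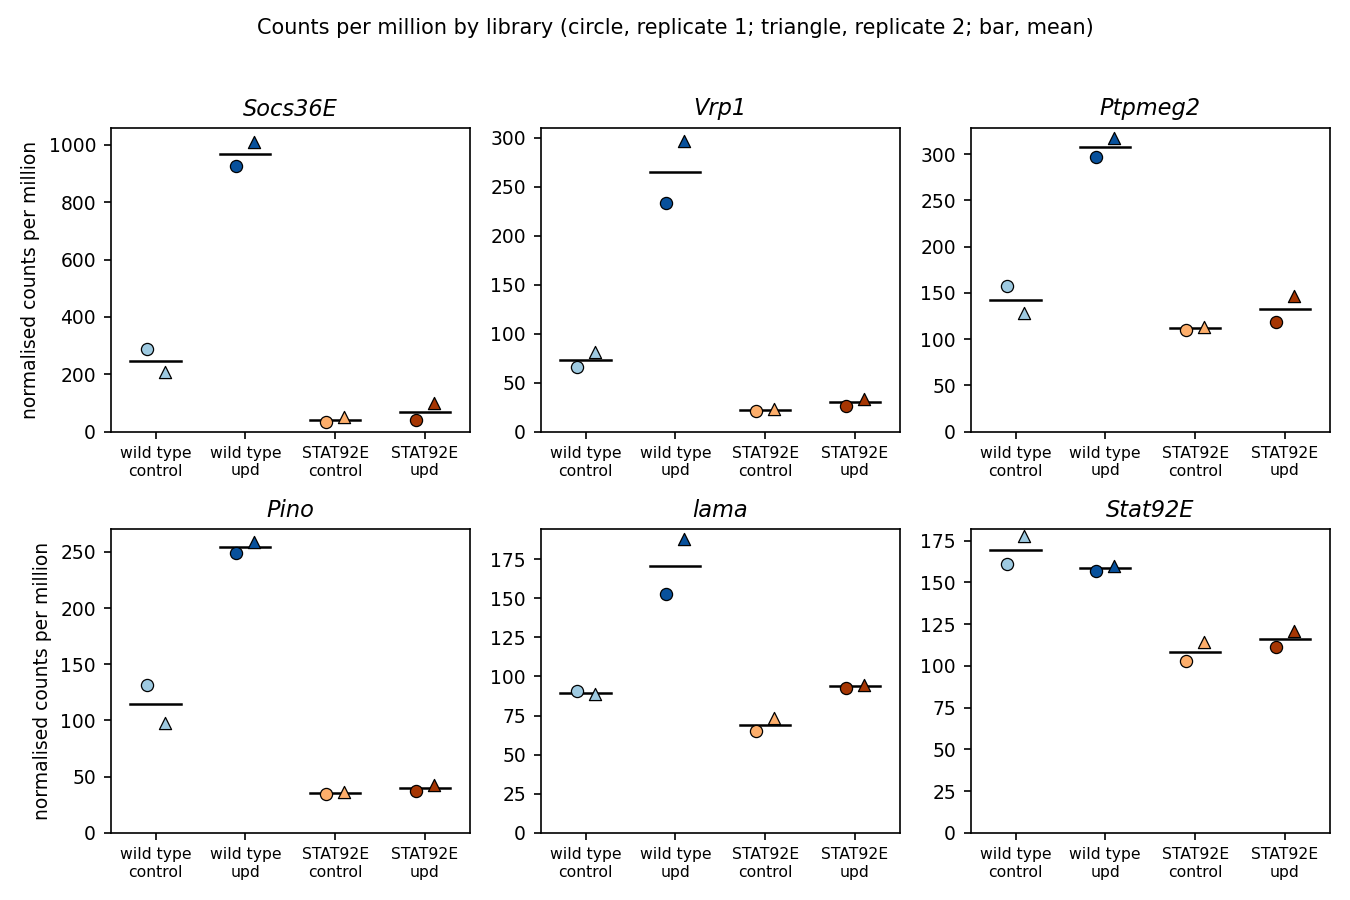
Normalised CPM (y axis, from 0) of 6 genes in each of the 8 libraries, by group (x axis); circles are replicate 1, triangles replicate 2 and bars group means. Socs36E stood at 287 and 208 CPM in wild-type cells in control media and at 927 and 1010 CPM with upd, while Stat92E stayed between 103 and 178 CPM in all libraries.

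An hour of upd raised Socs36E, Vrp1 and CG15097 in wild-type cells when libraries of like depth were compared. Socs36E, which encodes the feedback inhibitor of JAK/STAT signalling, went from 287 and 208 CPM in control media to 927 and 1010 CPM with upd. This is a log2 change of 1.99 ± 0.08 (SE) in the fit of the 4 wild-type libraries with depth batch as a term. The SEs of this fit, which was added after the data were seen, rest on 1 residual degree of freedom. Vrp1, which encodes a WASp-interacting regulator of actin, went from 65.4 and 81.1 CPM to 233 and 296 CPM. The uncharacterised gene CG15097 rose by 2.78 ± 0.10. Smaller rises were measured for mgl, which encodes an endocytic receptor of the LDL receptor family (1.32 ± 0.08), Pino (1.17 ± 0.08), the regulator of G protein signalling loco (1.14 ± 0.08), the tyrosine phosphatase gene Ptpmeg2 (1.12 ± 0.08), the zinc transporter gene foi (1.04 ± 0.08), CG6204 (1.00 ± 0.11) and lama (0.93 ± 0.09). In that fit 241 genes rose and 97 fell among 7748 tested, of which 28 rose and 3 fell more than 2-fold. Of the 241, 240 were higher with upd in both batches, which calling them on these libraries largely fixes in advance. With all libraries in 1 fit and the replicate number within genotype, 99 genes rose and 12 fell in wild-type cells. Within the shallow and the deep batch the log2 changes were 1.69 and 2.27 for Socs36E, 1.83 and 1.86 for Vrp1 and 0.91 and 1.40 for Pino. Among the genes that fell were TP53INP (-0.93 ± 0.13), stg, the Cdc25 phosphatase gene that drives entry into mitosis (-0.43 ± 0.08), and PRAS40, a component of TOR complex signalling (-0.68 ± 0.12).

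No gene passed in the edgeR test of all 8 libraries, which has no batch term. It called 0 of 8126 genes, 148 had an unadjusted p under 0.05 (88 higher and 60 lower with upd), and DESeq2 called 10. The 148 genes are fewer than the share of 0.05 that p-values give when nothing changes. They are therefore no sign of further changes. The test may be conservative here, so 0 calls do not show that no gene responded. Without a filter on low counts edgeR called 16, and with a robust prior 1. The genes with the lowest p were Vrp1 (log2 difference 1.85 ± 0.20, SE, n = 2 per group, adjusted p = 0.0693), Ptpmeg2 (1.11 ± 0.17, adjusted p = 0.263), Pino (1.15 ± 0.18, adjusted p = 0.263), CG6204 (1.00 ± 0.15, adjusted p = 0.263) and lama (0.93 ± 0.16, adjusted p = 0.357). On the lower side they were PRAS40 (-0.67 ± 0.20), lbk (-0.52 ± 0.15), Lsm11 (-0.66 ± 0.20) and CG13005 (-1.44 ± 0.46), each with an adjusted p of 1. The sugar transporter gene sut2 had 0 counts in both libraries with upd, which is at least 6.52-fold lower than in control media (at least 3.32-fold without replicate 2 of control media and 1.37-fold without replicate 2 with upd), also with an adjusted p of 1. The batch term was chosen after the data were seen, and its fit made 13 false calls among 188 on simulated data. Leaving out either mutant library with upd gave 2 calls in the fit without a batch term.

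Known JAK/STAT targets moved upwards as a group. Of 20 tested members of the list fixed beforehand, 17 had a positive log2 difference with upd, with a median of 0.22 (camera, adjusted p = 4.22e-06, and adjusted p = 0.21 with an estimated correlation). In the fit with depth batch 8 of them rose: Socs36E, lama, Mmp1 (0.70 ± 0.11), Tep2 (0.56 ± 0.10), Pvf3 (1.13 ± 0.21), Diap1 (0.41 ± 0.08), dally (0.69 ± 0.15) and zfh1 (0.30 ± 0.08). Mmp1 encodes a matrix metalloprotease, Tep2 a thioester protein of the immune response, Pvf3 a growth factor of the PDGF and VEGF family, Diap1 the inhibitor of apoptosis, dally a heparan sulphate proteoglycan and zfh1 a transcription factor. Pvf3 was higher with upd in both batches, but in the fit of all libraries its value was -0.11 without replicate 1 with upd. The list of pathway components had 14 of 18 members above 0 with a median of 0.16 (adjusted p = 0.00425, and 0.21 with an estimated correlation), and upd2, which encodes a ligand of the same family, rose by 1.27 ± 0.24 in the fit with depth batch. Adjusted over the list alone, 2 targets and 1 pathway component passed without a batch term, against 0 over all genes.

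Further lists had positive camera tests in wild-type cells. Targets of the stress kinase JNK had a median of 0.15 (adjusted p = 0.00184), with Jra (0.58 ± 0.08), Ets21C (0.86 ± 0.12) and the cell death gene rpr (1.06 ± 0.21) higher in the fit with depth batch. Immediate early and ERK targets had a median of 0.20 (adjusted p = 0.00336), and heat shock and protein folding genes one of 0.14 (adjusted p = 0.00425), with Hsp27 higher by 1.34 ± 0.29 in the fit with depth batch. The list of antimicrobial peptides and Toll/Imd feedback had a median of 0.15 (adjusted p = 0.0166). Its members that rose with depth batch in the fit were not peptides but pirk, an inhibitor of Imd signalling (1.02 ± 0.11), and dl, the Toll pathway's transcription factor (0.71 ± 0.10). Other lists that passed were ribosome biogenesis and Myc targets (0.14, adjusted p = 0.00425), extracellular matrix and integrins (0.15, adjusted p = 0.00425), Hippo targets (0.17, adjusted p = 0.0132), the circadian clock (0.11, adjusted p = 0.018), cytosolic ribosomal proteins (0.12, adjusted p = 3.33e-04) and mitochondrially encoded transcripts (0.18, adjusted p = 0.0287). With an estimated correlation the adjusted p was 0.21 for 6 of these 10 lists, 0.365 for immediate early and ERK targets, 0.531 for Hippo targets, 0.721 for ribosomal proteins and 0.724 for mitochondrially encoded transcripts. Adjusted over the list alone, 1 JNK target and 1 heat shock gene passed without a batch term and no member of the other 8 lists did. After quantile normalization, a list test added after the data were seen, ribosomal proteins (median 0.0312, adjusted p = 0.352) and mitochondrially encoded transcripts (median 0, adjusted p = 0.455) did not pass, and the median of heat shock genes was 0.0655 (adjusted p = 0.0299). Ribosomal and mitochondrial transcripts are abundant, and quantile normalization removes part of such shifts by construction. Their loss therefore does not decide whether they rose.

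All 12 lists that passed in wild-type cells, JAK/STAT targets and pathway included, lost their calls when the deep control library was left out, which also leaves the depths unequal between media. Without that library, replicate 2 of wild-type control media, the adjusted p was 0.0975 for JAK/STAT targets and between 0.0631 and 0.984 over the 12 lists, and mitochondrially encoded transcripts turned downwards. With the replicate number as a separate term within each genotype, chosen after the data were seen, all 12 passed (adjusted p = 2.24e-10 for JAK/STAT targets, 6.39e-04 for the pathway and 0.00458 at most). Without replicate 1 of wild-type cells with upd, 8 lists lost their call (adjusted p from 0.0757 to 0.906) and mitochondrially encoded transcripts were lower (adjusted p = 0.00191). Extracellular matrix and integrins also lost their call without replicate 1 of wild-type control media (adjusted p = 0.0857) and without replicate 2 of wild-type cells with upd (adjusted p = 0.244), and the antimicrobial list without the latter (adjusted p = 0.0789). Medians moved with the library left out. That of JAK/STAT targets was 0.342 without replicate 1 and 0.125 without replicate 2 of wild-type control media, and 0.0437 without replicate 1 with upd. In the same order those of ribosomal proteins were 0.275, 0.0133 and 0.0761, and those of mitochondrially encoded transcripts 0.534, -0.0922 and -0.357. Without replicate 1 with upd the medians of immediate early and ERK targets (-0.0316) and Hippo targets (-0.0614) lay below 0. Within batches, the median of JAK/STAT targets was 0.19 in the shallow and 0.29 in the deep libraries, and that of mitochondrially encoded transcripts was 0.32 and -0.04.

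In the mutant line Socs36E and Vrp1 were low, and upd made a smaller difference to them. Socs36E stood at 32.4 and 49.9 CPM in control media and at 39.8 and 98.0 CPM with upd (0.75 ± 0.39, adjusted p = 0.992, and a log2 difference of -0.046 without replicate 2 with upd). Vrp1 stood at 21.4 and 23.0 CPM and at 26.2 and 33.4 CPM (0.43 ± 0.20). The genes with the lowest p were others: mt:ND4L, a mitochondrially encoded subunit of respiratory complex I (1.15 ± 0.22), scyl (0.82 ± 0.18) and chrb (1.03 ± 0.26), both inhibitors of TOR signalling, ImpL2, a secreted antagonist of insulin-like peptides (0.85 ± 0.19), and the kinase gene fray (0.85 ± 0.21). On the lower side they were CG15093 (-1.66 ± 0.28), raskol (-0.74 ± 0.19), CG7408 (-0.77 ± 0.22), CG32115, with a ratio of counts of 11.6 (95% interval 1.65 to 503) between control media and upd, and Tsp68C, which had 0 counts with upd and was at least 3.86-fold lower (at least 2.09-fold and 1.77-fold without replicates 1 and 2 with upd). None of them passed. The edgeR test called 0 of 8126 genes, with a lowest adjusted p of 0.992 and 266 genes at an unadjusted p under 0.05 (186 higher and 80 lower), while DESeq2 called 2. The 266 genes are again fewer than the share of 0.05 that p-values give when nothing changes. With the replicate number as a separate term within each genotype, which was chosen after the data were seen and treats both lines alike, 313 genes rose and 154 fell. Socs36E (0.652 ± 0.138, adjusted p = 0.0079) and Vrp1 (0.415 ± 0.111, adjusted p = 0.0296) were among those that rose. The same term gave 99 and 12 genes for wild-type cells.

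Transcripts of the translation machinery and of mitochondria were higher with upd in the mutant line. Of 77 cytosolic ribosomal protein genes, 76 had a positive log2 difference, with a median of 0.35 (camera, adjusted p = 5.33e-24, and adjusted p = 0.616 with an estimated correlation), including RpL35A (1.17 ± 0.30) and RpL36A (0.72 ± 0.22). All 13 tested mitochondrially encoded transcripts had a positive difference, with a median of 0.62 (adjusted p = 3.94e-12, and 0.616 with an estimated correlation), alongside their larger share of all counts in the libraries with upd. Ribosome biogenesis and Myc targets had a median of 0.19 (adjusted p = 0.00526, and 0.616 with an estimated correlation), with Myc at 0.91 ± 0.46. Replication-dependent histones (median 0.35, adjusted p = 0.0216, and 0.651 with an estimated correlation) and insulin and FOXO targets (median 0.14, adjusted p = 0.0288, and 0.616 with an estimated correlation) also passed at the preset correlation. JAK/STAT targets were at the threshold, with 16 of 20 members above 0 and a median of 0.21 (adjusted p = 0.0496, and 0.712 with an estimated correlation). Limma on quantile-normalised log2(RPKM + 1), which changes the scale and the normalization together, gave smaller medians. For abundant transcripts part of this shrinkage is fixed by the normalization itself. They were 0.0948 for ribosomal proteins (camera, adjusted p = 0.00605) and 0.241 for mitochondrially encoded transcripts (adjusted p = 1.53e-04). In that setting histones (0.109, adjusted p = 0.277) and JAK/STAT targets (0.116, adjusted p = 0.0792) did not pass. No member of these 6 lists passed over all genes; adjusted over the list alone, 1 mitochondrially encoded transcript and 1 insulin and FOXO target did. Without replicate 1 of mutant cells with upd the median of ribosomal proteins was 0.122 (adjusted p = 6.22e-04), and that of mitochondrially encoded transcripts was 0.509 (adjusted p = 1.17e-05). Between libraries of equal replicate number the medians were 0.507 and 0.169 for ribosomal proteins and 0.827 and 0.429 for mitochondrially encoded transcripts. The camera test of the JAK/STAT list turned downwards without replicate 1 of mutant control media (median 0.0751, adjusted p = 0.996) or replicate 2 of mutant cells with upd (median -0.0164, adjusted p = 0.774), and lost its call without either wild-type library with upd (adjusted p = 0.0733 and 0.0569). Ribosome biogenesis lost its call without replicate 2 of mutant control media (adjusted p = 0.129) or replicate 1 of mutant cells with upd (median 0.0769, adjusted p = 0.148), histones without the latter (median 0.109, adjusted p = 0.111), and insulin and FOXO targets without these libraries (0.166 and 0.187) or replicate 2 with upd (0.0509).

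**Figure D2:**
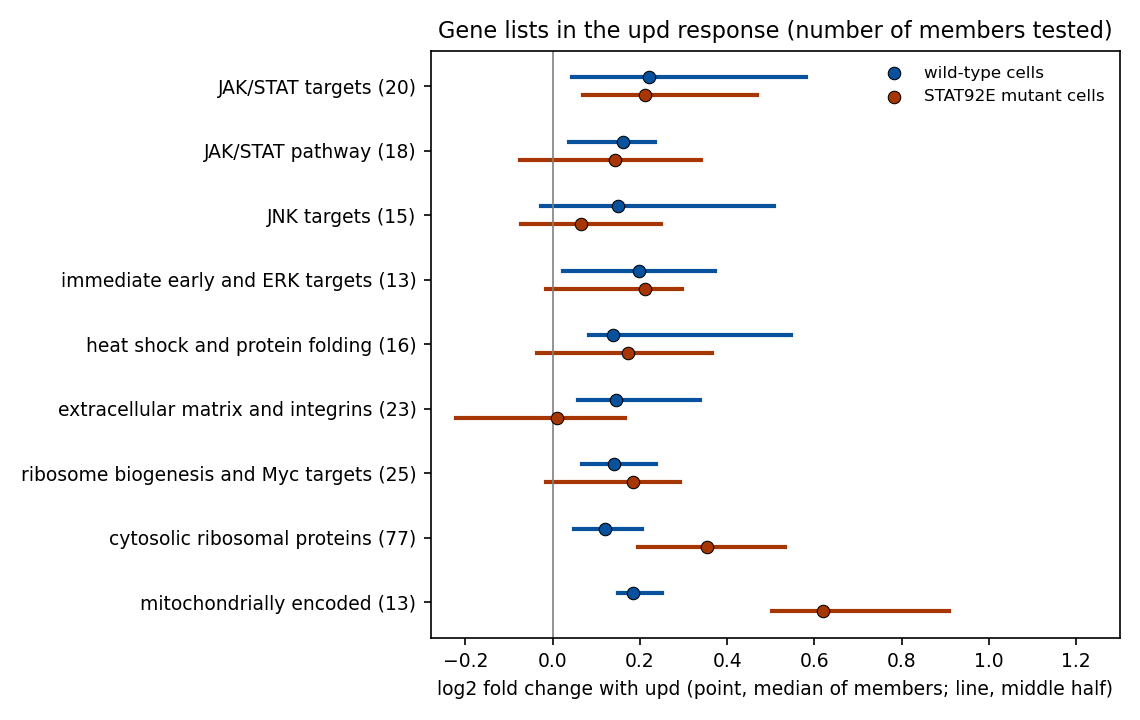
Log2 fold change with upd (x axis) of 9 gene lists (y axis, number of members tested in brackets) in wild-type and mutant cells; points are medians of the members and lines span their middle 50 percent. Mitochondrially encoded transcripts had a median of 0.18 in wild-type cells and 0.62 in the mutant line, and JAK/STAT targets 0.22 and 0.21.

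Whether the response differed between the lines was tested directly. The strongest genes of the wild-type response led the difference: Vrp1 (wild-type minus mutant log2 response 1.43 ± 0.28, SE), CG6204 (0.98 ± 0.22), CG15673 (3.31 ± 0.74), Pino (0.96 ± 0.25) and Ptpmeg2 (0.86 ± 0.24) had the lowest p among larger wild-type responses, and Socs36E stood at 1.22 ± 0.54. CG15673 went from 1.14 and 0.43 CPM to 7.39 and 6.12 CPM in wild-type cells, and from 4.11 and 2.13 CPM to 3.02 and 3.21 CPM in the mutant line. The kinase gene fray (-1.06 ± 0.29), Sesn, which encodes a stress-induced inhibitor of TOR signalling (-0.96 ± 0.29), and PRAS40 (-0.88 ± 0.28) leaned the other way. None passed: the edgeR interaction test called 0 of 8126 genes with a lowest adjusted p of 1, 88 genes had an unadjusted p under 0.05 (43 with a larger and 45 with a smaller wild-type response), and DESeq2 called 1. The 88 genes too are fewer than the share of 0.05 that p-values give when nothing changes. With the replicate number as a separate term within each genotype, 23 genes had a larger and 10 a smaller wild-type response. Among them were Vrp1 (1.44 ± 0.15, adjusted p = 2.02e-05), mgl and Socs36E (1.06 ± 0.15 and 1.34 ± 0.19, adjusted p = 7.49e-04 for both), and CG15097 (2.23 ± 0.37), Pino, Ptpmeg2 and CG6204, which had an adjusted p of 0.00474. On the other side were fray (-1.05 ± 0.15, adjusted p = 7.49e-04) and RpL36A (-0.81 ± 0.14, adjusted p = 0.00517).

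Ribosomal and mitochondrial transcripts had smaller responses in wild-type than in mutant cells with TMM scaling, and after quantile normalization the mitochondrial difference alone passed. The difference had a median of -0.21 over 77 cytosolic ribosomal protein genes (camera, adjusted p = 1.7e-08, and adjusted p = 0.974 with an estimated correlation) and of -0.47 over the 13 mitochondrially encoded transcripts (adjusted p = 3e-05, and 0.974 with an estimated correlation). These were the only ones of 29 lists to pass the interaction test without a replicate term; no member passed over all genes or adjusted over the list alone. After quantile normalization the medians were -0.0486 (adjusted p = 0.112) for ribosomal proteins and -0.212 (adjusted p = 0.0055) for mitochondrially encoded transcripts. That normalization shrinks shifts of abundant transcripts by construction, so the smaller medians do not decide whether the responses differed. JAK/STAT targets had a median difference of 0.10 and did not pass (adjusted p = 0.379), nor did pathway components (0.07, adjusted p = 0.537). With the replicate number as a separate term within each genotype, chosen after the data were seen, JAK/STAT targets (adjusted p = 0.0229), JNK targets (0.0322) and extracellular matrix and integrins (0.0159) passed as well. The ribosomal call was lost without replicate 1 of mutant cells with upd (median -0.0417, adjusted p = 0.799), and its median was -0.123 without replicate 1 and -0.322 without replicate 2 of wild-type control media and -0.406 without replicate 2 of mutant cells with upd. The mitochondrial call was lost without replicate 1 of mutant cells with upd (median -0.201, adjusted p = 0.143), replicate 1 of wild-type control media (-0.146, adjusted p = 0.177) or replicate 2 of wild-type cells with upd (-0.0807, adjusted p = 0.858). Its median was -0.975 without replicate 1 of wild-type cells with upd.

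The lines differed far more from each other than either did with upd. In control media the mutant line had almost none of the basement membrane collagens: Col4a1 (FBgn0000299, 2L, 5029609 to 5037279) stood at 376 and 583 CPM in wild-type cells and 1.34 and 0.73 CPM in the mutant line, a log2 difference of -8.81 ± 0.41 (SE, n = 2 per group, adjusted p = 2.51e-05), and its partner vkg fell by 6.70 ± 0.57 (adjusted p = 2.43e-04). The integrin alpha subunit gene mew fell by 6.48 ± 0.36, while mys, the gene of the beta subunit, rose by 1.25 ± 0.16. At the other end were genes with 0 counts in wild-type control libraries: dpr12, an immunoglobulin superfamily gene of the nervous system, at 80.4 and 65.7 CPM in the mutant line (at least 946-fold higher), CG11929 (at least 595-fold), the tetraspanin gene Tsp29Fb (at least 341-fold). Others were Elba3, a subunit of an insulator-binding complex (at least 289-fold), CG12782 (at least 277-fold), betaNACtes6 (at least 276-fold) and CG7881 (at least 144-fold). The extracellular matrix gene dpy and CG3251 had 1 count in wild-type control libraries, and their ratios of counts were 1870 (95% interval 336 to 74000) and 3470 (623 to 137000). Among the losses, Kank had 0 counts in the mutant line (at least 138-fold lower), and CCHa1-R, CG32572, Pgant2 and CG9498 were at least 54.8-fold, 60-fold, 33.7-fold and 25.6-fold lower. CG43063, eIF4B and FBgn0058178, an identifier without a symbol, had 1 count there, with ratios of 1690 (303 to 66900), 908 (163 to 35900) and 1580 (283 to 62400). CG40160 fell by 9.19 ± 0.71. In all, 266 genes were higher and 463 lower in the mutant line among 8126 (edgeR, adjusted p of 0.05), of which 151 and 356 differed more than 2-fold and 59 and 142 more than 8-fold. With the replicate number within genotype 1415 were higher and 1478 lower, but that fit leaves the spread between replicates of a line out of the error. By limma on log2(RPKM + 1), 45.6% of the calls were higher with quantile normalization and 43.7% without it, against 36.5% here. The count was 376 without wild-type replicate 1 of control media, 326 without wild-type replicate 2, 253 without mutant replicate 1 and 390 without mutant replicate 2. CCHa1-R, CG32572, Pgant2 and CG9498 lost their calls without mutant replicate 1 (adjusted p = 0.0779, 0.059, 0.0576 and 0.0621), where they were at least 24.1-fold, 26.4-fold, 14.8-fold and 11.3-fold lower. CCHa1-R also lost its call without mutant replicate 2 (adjusted p = 0.0524, at least 30.6-fold lower). These limits moved with the library left out. Without wild-type replicate 2 they were 196 for dpr12, 123 for CG11929, 70.5 for Tsp29Fb, 59.7 for Elba3, 57.3 for CG12782, 57 for betaNACtes6 and 29.7 for CG7881, and 124 for CCHa1-R and 110 for CG32572. Kank was at least 60.7-fold and 77.2-fold lower without mutant replicates 1 and 2, and without the latter CG32572, Pgant2 and CG9498 were at least 33.5-fold, 18.9-fold and 14.3-fold lower. All mutant libraries come from a single line, so changes due to the mutation and to the history of the line are not separated, and betaNACtes6 has near-identical copies whose reads may be shared.

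Lower in the mutant line as groups were the genes of matrix, blood cell identity and stress signalling. Of 23 tested genes of extracellular matrix and integrins, 7 fell and 1 rose, with a median of -1.01 (camera, adjusted p = 1.51e-09, and adjusted p = 0.0555 with an estimated correlation). Hemocyte markers, many of which are matrix genes as well, had 7 of 24 members lower and a median of -0.88 (adjusted p = 8.46e-09, and 0.163 with an estimated correlation), with Tig (-2.88 ± 0.39) and Glt (-3.37 ± 0.60) beside the collagens. JNK targets had 5 of 15 lower and a median of -0.78 (adjusted p = 9.27e-04, and 0.163 with an estimated correlation), among them puc, the phosphatase that restrains JNK (-1.39 ± 0.16), and scaf (-1.26 ± 0.18). JAK/STAT targets had 19 of 20 members below 0 and a median of -0.50 (adjusted p = 0.0014, and 0.429 with an estimated correlation). Those that fell were Socs36E (-2.59 ± 0.41), Tep2 (-5.28 ± 0.77), upd3 (-2.35 ± 0.52) and Stat92E itself. The antimicrobial and Toll/Imd list had 4 of 12 lower (median -1.04, adjusted p = 0.0134, and 0.24 with an estimated correlation): the cecropin gene CecC (-2.11 ± 0.24), PGRP-SA, and the Rel genes dl and Dif. Oxidative stress and detoxification genes had 6 of 26 lower (median -0.45, adjusted p = 0.00784, and 0.429 with an estimated correlation), led by the metallothionein gene MtnA, at 1130 and 935 CPM in wild-type cells and 107 and 27.7 CPM in the mutant line. Epithelial markers had 6 of 19 lower (median -0.23, adjusted p = 0.00784, and 0.351 with an estimated correlation), among them sdt (-2.26 ± 0.19), Nrg (-1.97 ± 0.18) and cora (-1.28 ± 0.14). The ecdysone list had 1 of 19 lower, MsrA (-2.62 ± 0.32), and a median of -0.43 (adjusted p = 0.0223, and 0.24 with an estimated correlation). Adjusted over the list alone, 14 matrix, 13 hemocyte, 7 JNK, 8 JAK/STAT, 4 antimicrobial, 9 oxidative stress, 7 epithelial and 1 ecdysone genes were lower, and 1 matrix gene was higher. Outside the lists that passed, the neuronal gene cpx rose by 3.32 ± 0.22 and bam, a germ line differentiation gene, fell by 4.19 ± 0.61. Epithelial markers did not pass after quantile normalization (median -0.181, adjusted p = 0.0731), and the antimicrobial median was then -0.377 (adjusted p = 0.00666). Numbers of lower genes fell with single control-media libraries left out. Without mutant replicate 1 they were 4 for matrix, 3 for hemocyte, 2 for JNK, 1 for JAK/STAT, 1 for antimicrobial, 3 for oxidative stress and 3 for epithelial genes. Without mutant replicate 2 they were 2 for JAK/STAT, 2 for antimicrobial and 3 for oxidative stress genes. Without wild-type replicate 1 they were 3 for JNK, 2 for JAK/STAT and 3 for oxidative stress genes, and without wild-type replicate 2 they were 4 for matrix, 2 for JNK and 3 for oxidative stress genes. Without replicate 2 of wild-type cells with upd 3 JNK targets were lower. Medians went to -0.447 for JNK targets and -0.117 for epithelial markers without wild-type replicate 1, to -0.373 for epithelial markers without wild-type replicate 2, and to -0.25 for oxidative stress genes without mutant replicate 1. Without mutant replicate 2 they were -1.24 for JNK targets and -0.775 for oxidative stress genes. Single libraries decided calls of these genes: Socs36E (-2.31), dl (-1.16), Glt (-2.90), Dif (-1.45), PGRP-SA (-0.85) and upd3 (-2.02) were not called without mutant replicate 1 of control media. Others were lost without mutant replicate 2 (MtnA -3.26, upd3 -2.75, Dif -1.52, PGRP-SA -0.89), wild-type replicate 1 (upd3 -1.72, the ecdysone list at adjusted p = 0.0735) or wild-type replicate 2 (Dif -1.36).

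The distal end of chromosome arm 2L, where Col4a1, Tep2, Pvf3 and Ets21C lie, was lower in the mutant line in its median. In control media 85.6% of its genes lay below the median of the other genes. Some went the other way: dpy, HP6, CG11929, Elba3 and CG3251, within 4477462 to 4722465, were higher. From position 9839 to 7984196, which holds 549 of the 1411 tested genes of the arm, the median log2 difference was -0.32 in control media and -0.32 with upd. Over the rest of the arm it was 0.07 in both media. The end of the segment was placed on the control-media libraries after their values were seen, and the libraries with upd were not used to place it. They come from the same lines, so a low value there is not a separate test.

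**Figure D3:**
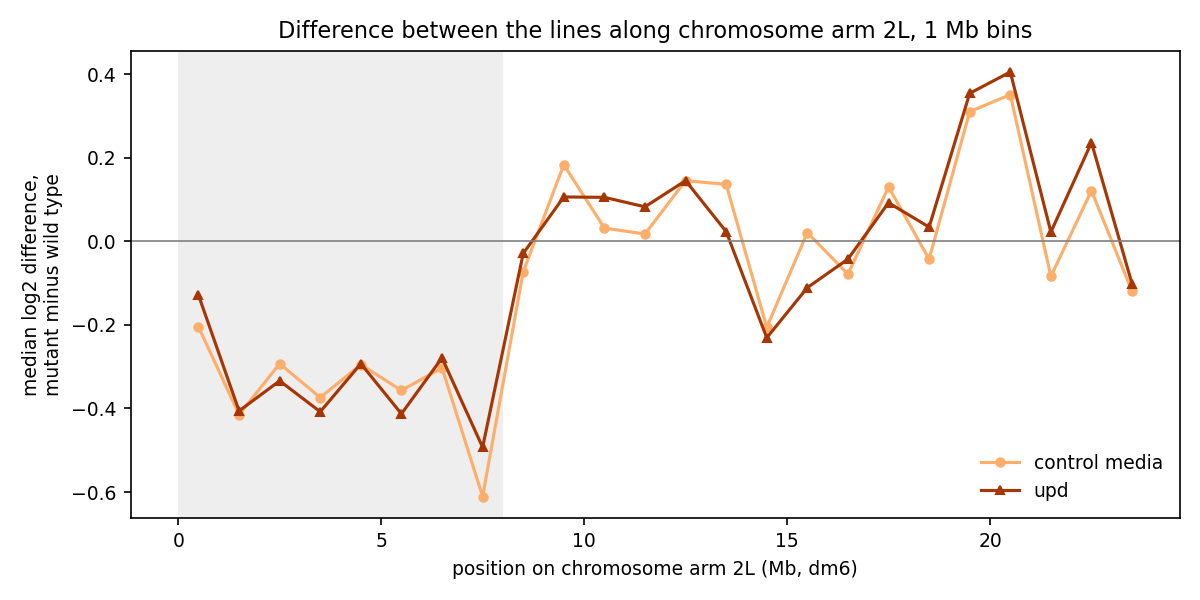
Median log2 difference between mutant and wild-type cells (y axis) of the tested genes in each 1 Mb bin along chromosome arm 2L (x axis, Mb), in control media and with upd. The grey span marks the distal segment, where the medians lie below 0 in both media.

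With upd the same comparison between lines gave a larger difference for Socs36E and similar values for the collagen genes. Socs36E was lower in the mutant line by a log2 difference of -3.81 ± 0.42 (SE, n = 2 per group, adjusted p = 9.99e-04). Col4a1 (-9.42 ± 0.43), vkg (-7.17 ± 0.58), Tep2 (-4.70 ± 0.71) and the innexin gene ogre (-9.92 ± 0.53) were lower as well, and mew had a ratio of counts of 351 (95% interval 120 to 1700) between the lines. AhcyL2, igl, CG18265 and CG6834 had 0 counts in the mutant line with upd and were at least 257-fold, 214-fold, 178-fold and 162-fold lower, and CG32115 had 1 count, a ratio of 1590 (286 to 63000). HP6, which lies inside the gene dpy, had 0 counts in wild-type cells with upd and 81.9 and 59.2 CPM in the mutant line (at least 916-fold higher), and betaNACtes3 had a ratio of 1420 (392 to 11700). Without replicate 2 of wild-type cells with upd the limits were 192 for HP6, 88.9 for igl, 92.4 for CG6834 and 268 for CG18265. For AhcyL2, igl, CG18265 and CG6834 they were 140, 116, 96.9 and 88 without mutant replicate 1 with upd, and 118, 98.4, 82.1 and 74.6 without mutant replicate 2. In total 324 genes were higher and 531 lower, of which 178 and 394 differed more than 2-fold and 64 and 163 more than 8-fold. With the replicate number within genotype 1365 genes were higher and 1433 lower, under the same limit as in control media. By limma on log2(RPKM + 1), 46.0% of the calls were higher with quantile normalization and 35.7% without it, against 37.9% here. In both media 604 genes were called, all in the same direction, 217 higher and 387 lower. Independent calls would give 10.6 and 30.3, but the comparisons are not independent. They share no libraries, yet they share the lines, the fit and its dispersions. Replicate differences within a line were also correlated between media (0.485 in wild-type and 0.514 in mutant cells). The overlap is therefore not a separate test. The count with upd was 474 without wild-type replicate 1, 382 without wild-type replicate 2 and 492 without mutant replicate 1 of the libraries with upd.

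With upd 7 lists passed, of which 6 had passed in control media. Extracellular matrix and integrins had 11 of 23 genes lower and 1 higher, with a median of -1.02 (camera, adjusted p = 7.53e-12), and this call held with an estimated correlation (adjusted p = 0.0368). Hemocyte markers had 9 of 24 lower (median -1.04, adjusted p = 1.23e-09, and 0.114 with an estimated correlation), including ush, a cofactor of GATA factors in blood cells (-1.76 ± 0.22). JNK targets had 9 of 15 lower (median -1.01, adjusted p = 5.29e-05, and 0.114 with an estimated correlation), with Ets21C at -2.11 ± 0.27. JAK/STAT targets had 6 of 20 lower (median -0.65, adjusted p = 1.59e-04, and 0.38 with an estimated correlation), and the antimicrobial and Toll/Imd list 4 of 12 lower and 1 higher, the Toll inhibitor gene cact (median -1.17, adjusted p = 0.00236, and 0.148 with an estimated correlation). Cytosolic ribosomal proteins had 65 of 77 members above 0 and a median of 0.20 (adjusted p = 0.0189, and 0.871 with an estimated correlation), while epithelial markers had 6 of 19 lower and a median of -0.04 (adjusted p = 0.0433, and 0.417 with an estimated correlation). With the replicate number within genotype epithelial markers did not pass (adjusted p = 0.0665). Adjusted over the list alone, 16 matrix, 14 hemocyte, 9 JNK, 13 JAK/STAT, 6 antimicrobial and 7 epithelial genes were lower, and 1 matrix, 1 hemocyte, 1 antimicrobial and 2 epithelial genes were higher. Oxidative stress and detoxification (median -0.36, adjusted p = 0.0616) and the ecdysone list (-0.31, adjusted p = 0.0674) did not pass with upd. They did with the replicate number within genotype (3.81e-05 and 0.00225), a term that leaves the spread between replicates of a line out of the error. Mitochondrially encoded transcripts had a median of -0.42 in control media (adjusted p = 0.291, and 1.96e-04 with that term) and of 0.17 with upd (adjusted p = 0.713), and ribosomal proteins had one of -0.00322 in control media. No ribosomal protein gene passed when adjusted over the list alone, against 3 over all genes. After quantile normalization the ribosomal (median 0.0877, adjusted p = 0.312) and epithelial lists (-0.016, adjusted p = 0.224) did not pass, and the antimicrobial median was -0.74. For the abundant ribosomal transcripts part of that shrinkage is fixed by the normalization. The ribosomal call was lost without replicate 2 of wild-type cells with upd (adjusted p = 0.0555) or replicate 1 of mutant cells with upd (median -0.0184, adjusted p = 0.793), and its median was 0.383 without replicate 2 of mutant cells with upd. The epithelial call was lost without any library except replicate 2 of wild-type cells with upd (adjusted p from 0.0537 to 0.152), and its median was 0.0458 without replicate 1 and -0.196 without replicate 2 of wild-type cells with upd. Among JAK/STAT targets, upd3 (-1.78), Mmp1 (-2.29) and Diap1 (-0.65) were not called without replicate 1 of wild-type cells with upd, nor upd3 (-2.10), Mmp1 (-2.996), Diap1 (-0.87) and lama (-0.70) without replicate 2. Without mutant replicate 1 with upd the calls of upd3 (-1.43), Mmp1 (-2.02), Diap1 (-0.69) and lama (-0.86) were lost, and without mutant replicate 2 that of Diap1 (-0.84). JAK/STAT targets lower numbered 3, 2 and 2 without the first 3 of these libraries, and JNK targets 4 without each of them. Without replicate 2 of wild-type cells with upd 5 hemocyte and 6 matrix genes were lower, and without mutant replicate 2 with upd 5 hemocyte genes were. Ribosomal protein genes called numbered 0 without the first 3 of these libraries, 5 without mutant replicate 2 with upd, and 1 without either mutant library of control media. No gene of the antimicrobial list was higher without replicate 2 of wild-type cells with upd or without either mutant library with upd.

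Genes that rose with upd in wild-type cells also leaned upwards in the mutant line. The 241 genes called with depth batch as a term had a median log2 response of 0.46 in wild-type cells and of 0.23 in the mutant line, where 80.5% were positive, against a median of 0.00 and 49.4% among 7788 other genes. They were selected on their wild-type values, so the medians of the lines do not measure a difference in strength. The 97 genes that fell had a median of -0.15 in the mutant line, with 28.9% positive. In the fit with the replicate number within genotype, 28 genes rose in both lines, where 3.81 would if calls were independent, 1 fell in both (0.227) and 1 was called in opposite directions (2.34). The calls are not independent, since they share the fit and its dispersions, so this overlap is not a separate test. With that term, chosen after the data were seen, Socs36E and Vrp1 were among the genes whose rise was larger in wild-type cells. The interaction test without it called 0 of 8126 genes. The gene zfh1 had nearly the same value in both lines (0.30 ± 0.08 and 0.28 ± 0.13). Across all 8126 genes, which are not independent replicates, the responses in the lines had a Pearson r of 0.0759 and a Spearman rho of 0.244, and across 5552 genes with a mean RPKM of at least 5 these were 0.333 and 0.393. Within a line, the log2(CPM + 0.5) differences of replicate 1 and of replicate 2 had a rho of 0.243 in wild-type and 0.322 in mutant cells. These differences rest on 1 library per medium, against 2 in the rho between lines. The values within and between lines are therefore not alike and do not show that the lines agree as well as replicates. The rho between lines turned negative without replicate 2 of wild-type control media (-0.0708) or replicate 1 of wild-type cells with upd (-0.0877). It was 0.367 without replicate 1 of wild-type control media, 0.364 without replicate 2 of wild-type cells with upd and 0.153 without replicate 1 of mutant cells with upd.

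**Figure D4:**
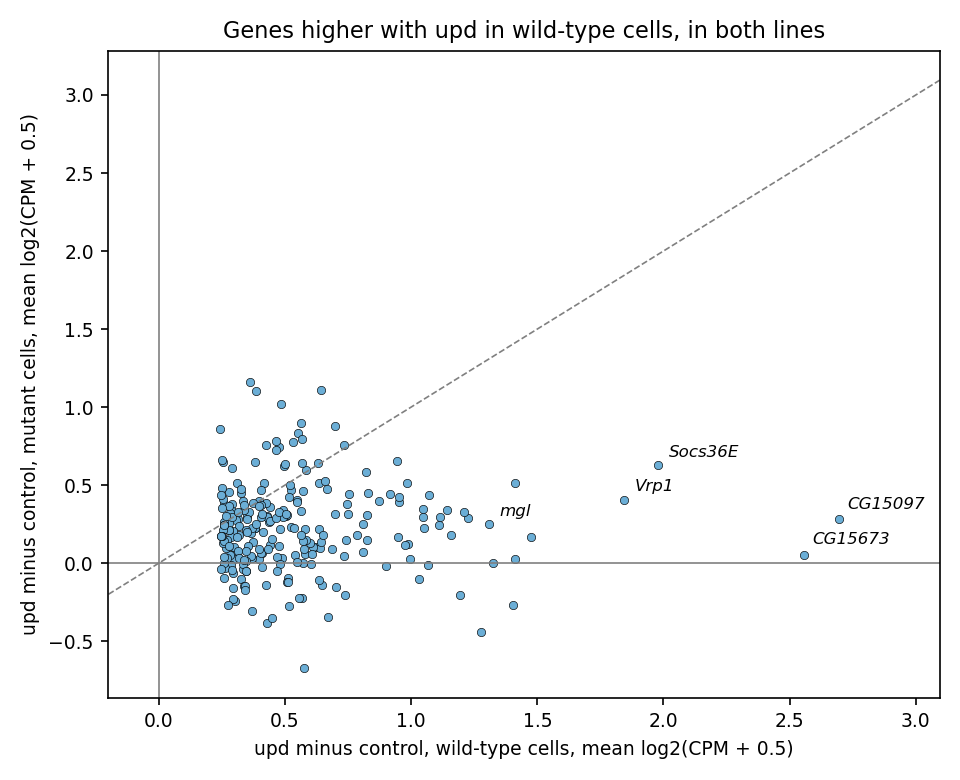
Mean difference of log2(CPM + 0.5) between upd and control media in wild-type (x axis) and mutant cells (y axis) for the 241 genes called higher with upd in wild-type cells with depth batch as a term; each point is a gene and the dashed line marks equal values. Most genes lie above 0 in the mutant line, and Socs36E, Vrp1, CG15097 and CG15673 lie far below the dashed line.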

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

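The tests of mixed-in wild-type cells, of a deviating library, of a copy number difference and of lists after quantile normalization were chosen only after the result was seen. Intervals of medians and of rho in this part come from resampling genes, which are not independent. They leave out the spread between libraries, so what is argued against below is so for these libraries only. The difference in response between the lines was tested with camera on the interaction term for 29 lists. The 2 that passed are taken up here: mitochondrially encoded transcripts (adjusted p = 3e-05) and cytosolic ribosomal proteins (adjusted p = 1.7e-08). With an estimated correlation the adjusted p was 0.974 for both. After quantile normalization it was 0.0055 (median -0.212) and 0.112 (median -0.0486). Quantile normalization removes part of a shift of abundant transcripts by construction, so smaller values after it do not decide here.

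Ribosomal protein and mitochondrially encoded transcripts were higher with upd in the mutant line, with a median log2 response of 0.38 (95% interval 0.31 to 0.47) over 90 members of both lists, and with smaller medians of 0.0948 and 0.241 after quantile normalization. With all libraries, short transcripts as the whole cause are argued against by 526 highly expressed genes matched on length (median length 893 for both sets, each gene weighted by its number of matches), whose median was 0.112 (0.0808 to 0.136). Without replicate 1 of mutant cells with upd the 90 members had an interval of 0.1066 to 0.1955, and the matched genes were not examined without it. One deviating library stays open for both lists: without replicate 1 of mutant cells with upd the median was 0.122 (0.0934 to 0.157), against 0.353 with all libraries, for ribosomal proteins. For mitochondrially encoded transcripts it was 0.509 (0.295 to 0.651) against 0.619, where the interval over the 13 members reaches below 0.5 of 0.619, the bound set against this explanation. A response to upd that does not need STAT92E stays open as well and was not tested.

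Genes that rose with upd in wild-type cells also leaned upwards in the mutant line, with a median of 0.23 (95% interval 0.20 to 0.28) over 241 genes. Wild-type cells in the mutant cultures are argued against, since a share of 24.6% would be needed. Among transcripts of at least 50 CPM in wild-type cells, the 10 with the lowest ratio of mutant to wild-type level were taken. They stood at a median of 0.6% of their wild-type level in the mutant libraries and at 1.77% at most. They were picked for being low, because mixed-in cells would bring every such transcript up to their share. Gene length or expression level is argued against by 3073 matched genes with a median of 0.0119 (-3.56e-04 to 0.0257). Remaining STAT92E activity might give a weaker response of the same genes, and this stays open: Spearman's rho between the lines over the called genes was 0.129 (-0.00862 to 0.253), which lies below the 0.3 set for this explanation but not below the 0.1 set against it. A response that bypasses STAT92E, or to something else in the ligand's medium, was not tested. Either could give the same rho as remaining STAT92E activity, so the rho cannot tell these apart.

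Genes of distal 2L were lower in the mutant line, with medians of -0.32 (95% interval -0.35 to -0.29) in control media and -0.32 (-0.36 to -0.29) with upd. Gene length or expression level is argued against, since genes elsewhere matched on both had a median of 0.0557 (0.0437 to 0.0672) with upd. A copy number difference of the segment stays a hypothesis. With upd, 82.9% of its genes lay below the median of the other genes, and 0 of 4378 equally long runs on the other arms were as low. The lowest of those runs had a median of -0.02, and runs of that length cannot show shorter blocks. Those runs overlap, the segment was picked for its low values, and the libraries with upd come from the same lines. The values therefore cannot decide for a copy number difference. Copy number itself was not measured, and whether such a difference came with the mutation or with the history of the line was not tested.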

How the results depend on the processing

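The fit with depth batch, those with the replicate number within genotype and list tests after quantile normalization were chosen only after the data were seen. So was limma on log2(RPKM + 1) as an alternative, which the plan held for tables without counts. A block by replicate number assumes that numbers pair libraries. Within a line, gene by gene differences between replicates 1 and 2 had a correlation of 0.485 (wild type) and 0.514 (mutant) between media, against -0.0595 to 0.0605 across lines.

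The count of genes for upd in wild-type cells, 0 in the edgeR test of all libraries, was 16 without a filter on low counts, 1 with a robust prior, 1 with the replicate block, 10 by DESeq2, 111 with the replicate block within genotype and 338 with depth batch. It was 0 to 2 with a library left out. In the mutant line it was 18 without a filter, 2 by DESeq2, 467 with the replicate block within genotype and 471 when the mutant libraries were fitted alone with a replicate block. The difference between lines gave 4 genes without a filter, 1 by DESeq2 and 33 with the replicate block within genotype.

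For the genotype effect in control media, 729 genes became 1294 without a filter, 472 with a mean RPKM of at least 5, where fewer genes are tested, 1247 with the replicate block, 1138 by DESeq2 and 2893 with the block within genotype. For the genotype effect with upd, 855 became 1429 without a filter, 1386 with the replicate block and 2798 with the block within genotype. The counts with the block within genotype leave the spread between replicates of a line out of the error, so they are not like the other counts. Leaving out a library gave 253 to 782 genes in control media and 382 to 774 with upd, where groups of 1 library are assumed to vary like the others. DESeq2 kept 727 of the 729 calls and 854 of the 855. The cause of the other changes was not tested.

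With an estimated correlation the adjusted p of JAK/STAT targets was 0.21 for upd in wild-type cells, 0.429 between the lines in control media and 0.38 with upd. For ribosomal proteins and mitochondrially encoded transcripts it was 0.616 in the mutant line and 0.974 for the difference between lines. For hemocyte markers it was 0.163 in control media and 0.114 with upd, and for extracellular matrix in control media 0.0555. After quantile normalization 8 of the 35 list calls were lost, among them ribosomal proteins for the difference between lines (0.112). With the block within genotype 1 call was lost, that of epithelial markers between the lines with upd (adjusted p = 0.0665). In wild-type cells 3 lists passed newly, 5 in the mutant line, 3 for the difference, 5 between the lines in control media and 7 with upd. With a library left out, the adjusted p ranged from 1.69e-07 to 0.0975 for JAK/STAT targets and from 1.07e-11 to 0.509 for mitochondrially encoded transcripts in wild-type cells. It ranged from 4.2e-06 to 0.996 for JAK/STAT targets in the mutant line, and for the difference between lines from 8.27e-18 to 0.858 for mitochondrially encoded transcripts and from 9.52e-18 to 0.799 for ribosomal proteins.

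The rho between the responses, 0.244, was 0.393 at a mean RPKM of at least 5, 0.323 with a pseudocount of 0.1 RPKM, and -0.0877 to 0.367 with a library left out. The log2 difference of Stat92E ranged from -0.721 to -0.57. The upd response of Pvf3 in wild-type cells ranged from -0.11 to 2.51 and turned without replicate 1 with upd. In the mutant line Socs36E ranged from -0.046 to 1.25 and Tep2 from -0.46 to 2.56, each turning without replicate 2 with upd. None of these responses passed in the fit of all libraries.

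Under the alternatives fixed in advance, named genes kept direction and side of the threshold in 1463 cases, passed newly in 41 and lost their call in 30. With a library left out these counts were 1078, 4 and 75, and 3 turned. Median-of-ratios scaling and limma on quantile-normalised log2(RPKM + 1) shifted the median of all genes by at most 0.0538. The latter, which changes the test, the scale and the normalization together, moved some list medians further. For ribosomal and mitochondrial transcripts, which are abundant, part of this move is fixed by quantile normalization itself. Ribosomal proteins in the mutant line went from 0.353 to 0.0948, and mitochondrially encoded transcripts in wild-type cells from 0.184 to 0. The antimicrobial list between the lines went from -1.04 to -0.377 in control media and from -1.17 to -0.74 with upd. Depth limits the folds against groups without counts, and the fit of all libraries recovered 1.02% of the 2-fold changes simulated in the response difference from a model with replicate terms.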

Other observations

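The test of neighbouring genes was chosen only after the result was seen. Genes that differed between the lines in control media lay beside each other: 113 pairs of neighbouring tested genes were called in the same direction, against a mean of 34.9 and a highest value of 63 over shuffles of the calls within chromosome arms (one-sided permutation p = 1e-05, the smallest the shuffles can give). Random placement along the chromosomes is argued against by this value, and what joins the neighbours was not tested.

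On X, 10 genes between 2552206 and 2633672 were higher in the mutant line, among them Klp3A, a kinesin of the spindle (1.496 ± 0.163), Zw10, a kinetochore gene (1.72 ± 0.25), and wds. On 2L, dpy, HP6, CG11929, Elba3 and CG3251 were higher within 4477462 to 4722465, inside the distal segment whose median was lower. Also on 2L, Idgf1 (-4.997 ± 0.604), Idgf2 (-4.31 ± 0.41) and Idgf3, a family of secreted chitinase-like growth factors, were lower within 16400175 to 16532877. On 3R, Stat92E is next to the metallothionein genes MtnB, MtnE and MtnD, and the 4 genes were lower together within 20503102 to 20552311. MtnE (-5.197 ± 0.812) and MtnD (-4.5 ± 0.87) fell, and MtnB had a ratio of counts of 147 (95% interval 26 to 5840). MtnA, which lies elsewhere on 3R, was lower as well. Calls were lost for wds (0.86) without mutant replicate 1 of control media and for MtnA (-3.26) without mutant replicate 2. They were lost for MtnD (-4.27) without wild-type replicate 2, and for Idgf3 without wild-type replicate 2 (-1.21), mutant replicate 1 (-1.69) or mutant replicate 2 (-1.81).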
